A study of Drosophila melanogaster with 3 samples.

How the data were processed

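The samples were 3 biological replicates of TF ChIP-seq on whole Drosophila melanogaster embryos, 0 to 24 hours old and of mixed sex, from a transgenic line expressing CrebB with a green fluorescent protein tag. Per the labels, chromatin was sheared by sonication and the size range was 200 to 800. The replicate numbers were taken from the labels. The antibody label puts all 3 samples in 1 group, while a description field of the same samples speaks of input controls; the values were read as ChIP of CrebB, and this reading could not be checked against reads.

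Per the companion text deposited with the lists, the authors called peaks on each replicate's alignment against 1 control alignment and, for the pooled list, on the 3 alignments together, on assembly dm6. The optimal list derives, per the same text, from the 3 replicate lists and the pooled list by an IDR threshold. The aligner, the peak caller and their versions were not given in the sources used here. In each deposited list a peak has the caller's own signal value, which has no stated scale and was used only to rank, filter or correlate peaks, and a −log10 q-value, which the authors' lists give per peak. The summit offset of each peak, deposited as another column, set the summit position. The score column is 0 and the p-value column is -1 for every peak, and neither was used. Each replicate list and the pooled list hold 30000 peaks, so the lists have a fixed length. The optimal list was found to equal the 3915 peaks of highest signal in the pooled list. Signal values of different lists were not compared as levels.

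Depth is unknown, since the lists give no read numbers. Wilson and exact binomial intervals at the 95% level therefore cover the counting of peaks or genes only, and p-values over peaks measure these pooled lists, with the spread between replicates given where the lists of single replicates allow it.

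Coordinates are those of the deposited lists on dm6, written from 1. Gene models were the Ensembl annotation, release 115, of the same assembly, and sequence was the RefSeq copy of Release 6; all peak ends lay within the chromosome lengths. In all, 19607 TSSs of 13945 protein-coding genes on chromosomes 2, 3, 4 and X were used. A peak was called a promoter peak when its summit lay within 500 bp of one of them. Other summits were assigned, in this order, to 5' UTR, 3' UTR, coding exon, intron or intergenic sequence. The pooled-list peaks used as a background were the 25301 that overlap no optimal peak, which leaves out peaks of lower rank that overlap one. For these classes 100 draws of random positions were made, and 1000 for the promoter share.

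Support by a replicate meant a summit within 100 bp among the replicate's 3915 peaks of highest signal. For IDR, the peaks of 2 replicates were matched when each was the other's overlapping peak with the nearest summit, and a mixture of 2 Gaussian copula components was fitted to the ranks of the signal by expectation maximisation from 4 starting points, keeping the best likelihood. Pairs with a fitted correlation under 0.2 would have given no reproducible peaks. Motif and 8-mer presence within 100 bp of the summit was compared with the window centred 1000 bp to the right of the same summit by an exact two-sided McNemar test. Gene lists were tested with Fisher's exact test, two-sided, over all protein-coding genes. Adjusted p-values are Benjamini-Hochberg values, over 15 motifs, over all 8-mers or over 22 lists. The difference in CRE share by signal used a permutation test with 100000 resamples. Of the symbols in the lists, 5 were matched by a synonym and 1, of the germline list, had no match.

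Before the data were examined, the lists, the motifs, the tests, most alternatives and the rule for named genes were fixed. The rule took every optimal peak within 2000 bp of CrebB, the 20 promoter peaks of highest signal supported by all 3 replicates, the 10 such peaks of highest signal with TGACGTCA (8 existed), up to 4 members of each list with the highest signal and all bound members of the cAMP and clock lists, and the 10 8-mers of smallest p. Of the 20 promoter peaks, 1 is not reported here. The alternatives changed the summit distance (50 or 200 bp, or 50% reciprocal overlap), the list depth, the IDR threshold (0.01 or 0.02) and matching, the motif window (50 or 250 bp) and its background, the TSS distance (250 or 1000 bp), the peak set (the 1957 of highest signal, those supported by all 3 replicates, those over 500 bp from a TSS) and the replicates used. Leaving out a replicate meant using the optimal peaks supported by the other two, or the pair of the other two.

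The IDR fit, the 8-mer search, the CRE test and the gene list test were tested on simulated data. With 48.0% of 16000 simulated pairs reproducible, the IDR fit gave 48.1%, 5.21% of the pairs called at 0.05 were irreproducible, and 55.9% of the reproducible pairs were called (40.5% where 25.5% of the pairs were reproducible), so a count at this threshold leaves out many reproducible peaks. A first version of the fit, with 1 starting point and no limit on the correlation, called all unrelated pairs in this test. The 4 starting points and the limit of 0.2 were added after that. Among 16000 unrelated pairs 0 were then called, which is the work of the limit, since without it the fit from 4 starting points called all 16000 (fitted correlation -0.00841). The fitted correlations of the 3 replicate pairs were 0.881, 0.823 and 0.831, so the limit changed none of their counts. In 3915 random windows 0 8-mers were called, and 14 of 20 8-mers planted in 1% of windows and 20 of 20 planted in 2% were recovered. These windows were random genome positions, so the test does not cover a difference in GC content between summits and distant points. The CRE palindrome planted in 1% of windows was called in 50 of 50 runs. That is a larger rise than the 0.587% against 0.358% found at the optimal peaks, so power at the size found was not tested. In random gene sets 0 of 880 list tests passed. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.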

Results

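Sites bound by CrebB, the fly homologue of the cAMP-responsive basic leucine zipper (bZIP) transcription factor CREB, were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Drosophila melanogaster embryos of mixed sex collected 0 to 24 hours after egg laying. The embryos carried a transgene that expresses CrebB fused to green fluorescent protein. The series held 1 group of 3 biological replicates, so no group of samples was compared with another, and the comparisons below set peaks against background positions, against neighbouring sequence and between replicates. Each replicate had its own peak list of 30000 peaks, and the 3 replicates together had a pooled list of 30000 peaks. The list of peaks past the authors' reproducibility threshold, called optimal peaks here, held 3915 peaks with a median width of 396 bp. Their widths summed to 1.02% of the length of chromosomes 2, 3, 4 and X. The number of reads per sample was not given in the sources used here, so the depth is unknown. The replicate lists ran far into the background: 10907, 9441 and 8744 of the peaks of replicates 1, 2 and 3 had a q-value under 0.05. A description field calls the libraries input controls, while the antibody, assay and source labels describe ChIP of CrebB, and the samples were grouped by the antibody label.

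The strongest CrebB peaks recurred in all 3 replicates, while weaker optimal peaks did so less often. Of the 3915 optimal peaks, 1959 (50.04%, 95% Wilson interval 48.5% to 51.6%) had a summit within 100 bp in the 3915 highest-signal peaks of each replicate. Random positions on the same chromosomes gave 9.59 such peaks on average and at most 22 in 1000 draws, but the optimal list was derived from these same replicate lists for reproducibility, so its recurrence in them is no independent test. Single replicates supported 78.4%, 77.5% and 73.4% of the optimal peaks, in the order of replicates 1, 2 and 3, and 66 peaks (1.69%) had support from none. Among the first 1000 ranks of the pooled list 96.5% of peaks were supported, and among ranks 2001 to 3000 the share was 24.4%. With the full replicate lists these shares were 97.6% and 84.4%. The count of supported peaks depended on how deep the replicate lists were read: 1104 peaks with the first 1957 ranks and 3052 with the first 7830.

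**Figure D1:**
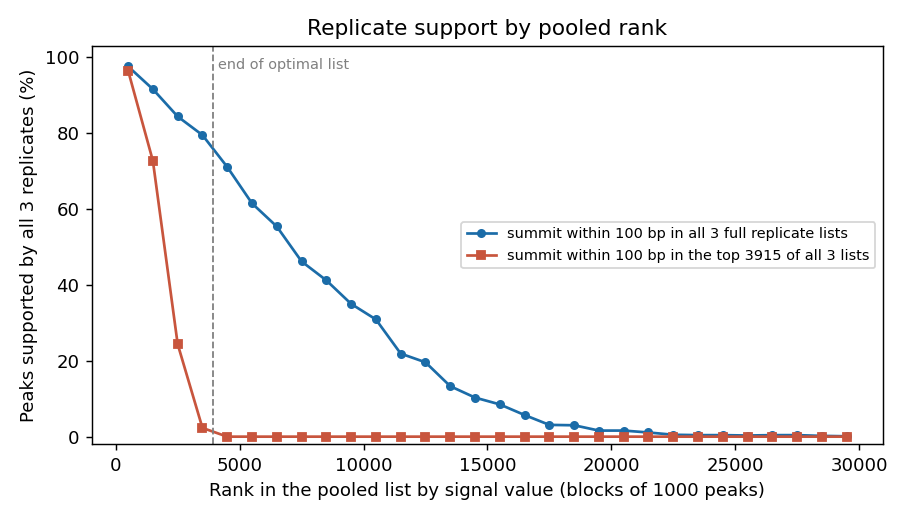
Share of pooled-list peaks (%) with a summit within 100 bp in all 3 replicates, against rank by the authors' signal value in blocks of 1000, using the full replicate lists (circles) or their top 3915 peaks (squares). With the full lists the share runs from 97.6% in the first block to 0.1% in the last, and the dashed line marks the end of the optimal list at rank 3915.

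Replicates were also compared in pairs with the irreproducible discovery rate (IDR), which models the ranks of matched peaks as a mixture of reproducible and irreproducible pairs. At an IDR of 0.05, 4920 peaks passed for replicates 1 and 2, 4242 for replicates 1 and 3, and 4255 for replicates 2 and 3 (mean 4472 ± 388, SD over 3 pairs). The fitted share of reproducible pairs lay between 47.5% and 48.5%. At an IDR of 0.01 the median pair kept 2536 peaks. Across the optimal peaks, which are not independent replicates, Spearman's rho of the signal values was 0.686 for replicates 1 and 2, 0.499 for replicates 1 and 3 and 0.532 for replicates 2 and 3. Replicates 1 and 2 ranked the optimal peaks more alike than either did with replicate 3.

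CrebB peaks lay mostly at gene starts. Of the 3915 optimal peaks, 2135 (54.5%, Wilson interval 53.0% to 56.1%) had the summit within 500 bp of the transcription start site (TSS) of a protein-coding gene, against 11.5% of random positions on the same chromosomes (one-sided permutation p = 0.001, the smallest 1000 draws can give). The 25301 peaks of the pooled list that overlap no optimal peak had 27.0% of summits there. Over the 3915 strongest peaks of each replicate the promoter share was 54.5% ± 0.532 (SD, n = 3). Outside promoters, 1240 summits (31.7%) lay in introns and 470 (12.0%) between genes, and these shares stood at 39.2% and 30.0% for random positions. Coding exons held 7 summits (0.179%), against 13.3% of random positions and 8.59% of these 25301 peaks. The 3' UTRs held 34 (0.868%), against 5.06%, and the 5' UTRs beyond 500 bp of a TSS held 29 (0.741%), against 0.774%. A protein-coding TSS lay a median of 319 bp from the summit.

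The CrebB gene itself carried 7 optimal peaks. The gene (FBgn0265784) lies on chromosome X from 18366357 to 18377864 on the + strand of dm6. The peak of highest signal there (998.1, rank 80 of the optimal list) spanned 18367172 to 18367465 in an intron, with its summit 762 bp downstream of the nearest TSS. Another intronic peak at 18368140 to 18368363 had a signal of 478.3. These were the only peaks of the locus that all 3 replicates supported. The peak at 18371478 to 18371873, with a signal of 399.4 and its summit 415 bp downstream of an internal TSS, was the only one with the palindromic cAMP response element TGACGTCA within 100 bp of its summit. Replicates 1 and 2 supported it, and in replicate 3 the nearest summit within 100 bp stood at rank 11006. When summits up to 200 bp apart were counted, all 3 replicates supported this peak. The other 4 peaks had signals from 153.0 to 247.0, and replicate 3 had no summit within 100 bp of them in its list.

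**Figure D2:**
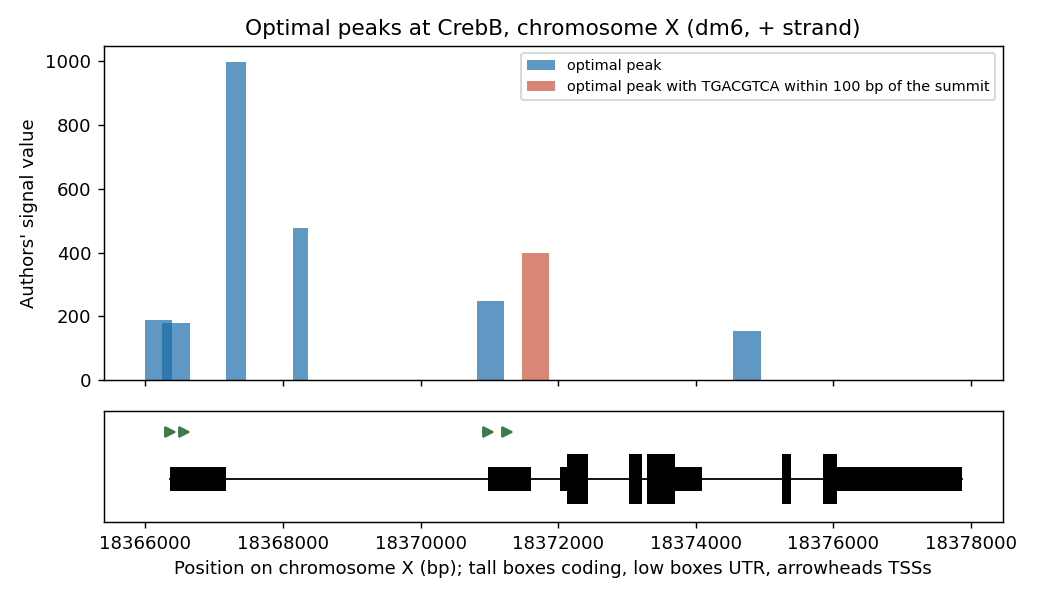
Optimal peaks at CrebB (upper panel: peak extent in bp on chromosome X of dm6 against the authors' signal value) above the gene's exons, with coding parts as tall boxes, UTRs as low boxes and TSSs as arrowheads. The 7 peaks have signals from 153.0 to 998.1, and the red bar is the peak with TGACGTCA.

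The strongest promoter peaks were at CG14100, Ugalt, px and Gapdh2. Of the optimal peaks, 1052 lay within 500 bp of a TSS and were supported by all 3 replicates. The highest signal among these (2859.8, rank 3) was at CG14100, chromosome 3L from 19590449 to 19590796, with the summit 95 bp upstream of the TSS in intergenic sequence. It ranked 4, 2 and 3 in replicates 1, 2 and 3. Next were Ugalt, a UDP-galactose transporter (X, 2703704 to 2704081, signal 2620.3, summit 43 bp upstream), px (2R, 22514130 to 22514471, 2455.2), and Gapdh2, a glycolytic enzyme (X, 15867799 to 15868151, 2217.8, summit 173 bp upstream). The peak between CenG1A and mRpS23 (2L, 13835309 to 13835638) had a signal of 2203.4, and that between Art3 and mRpS10 (3R, 15229373 to 15229702) had 2048.3. mRpS23, mRpS10 and mRpL41 (1697.2) encode mitochondrial ribosomal proteins. The Polycomb group gene ph-p had a peak of 2094.6 whose summit lay in an intron, 484 bp upstream of the nearest TSS of ph-p. Others of the 20 strongest were at CG1888, CG11309 with CG7632, CG9147 with Fbw5, PNPase, which encodes an RNA-degrading enzyme, CG18549, the chromatin protein gene Chro with Ssl1, CG1635, Pdrg1 with Pal1, the kinase gene gish, Fkbp14 and the ribosome biogenesis factor gene eIF6. Their signals ran from 1379.1 at eIF6 to 2071.7 at CG1888. None of the 20 peaks had TGACGTCA within 100 bp of the summit, and 1, at eIF6, had a DRE or M1BP site.

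Peaks with the CRE palindrome TGACGTCA, the sequence CREB proteins recognise, were rare. It lay within 100 bp of 23 of the 3915 summits (0.587%, Wilson interval 0.392% to 0.880%), against 14 windows (0.358%) centred 1000 bp to the right of the same summits (exact McNemar test, two-sided, p = 0.188, adjusted p = 0.256 over 15 motifs). In the 3915 strongest peaks of each replicate the share was 0.690% ± 0.184 at summits and 0.332% ± 0.0442 in the distant windows (SD, n = 3), and it was higher at summits in 3 of 3 replicates. The 978 peaks of highest signal held 8 palindromes and the 978 of lowest signal held 6 (permutation test, two-sided, p = 0.791). Against a window 2000 bp away, a comparison chosen after the values were seen, the difference turned to -0.0255 percentage points (exact test, adjusted p = 1, against 0.247 to 1 over all alternatives). Of the 1052 promoter peaks supported by all 3 replicates, 8 carried the palindrome. The strongest was between l(2)gd1, which acts in endosomal sorting, and Reps (2L, 11106688 to 11106958, signal 787.8, summit 99 bp upstream of l(2)gd1). Then came Vps33B with Fur1 (618.5), the vacuolar ATPase subunit gene Vha55 with Snx3 (446.6), Cmpk (351.2), PIG-Q with the splicing factor gene U2af50 (350.9), the G protein gene Galphai (232.8), the RNA-binding protein gene Unr (221.4) and the Rab escort protein gene Rep with Oseg6 (213.9).

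The DRE and the M1BP site were more frequent at the summits. The DRE, the element bound by the housekeeping promoter factor DREF, lay within 100 bp of 152 summits (3.88%, Wilson interval 3.32% to 4.53%) and of 21 distant points (0.536%), a 7.24-fold difference (exact McNemar test, adjusted p = 1.6e-24). The binding sequence of M1BP was found at 87 summits (2.22%) and 8 distant points (0.204%), a 10.9-fold difference (exact test, adjusted p = 5.06e-17). Against GC-matched pooled-list peaks that overlap no optimal peak the differences were smaller: 3.88% against 2.22% for the DRE (1.75-fold, Fisher's exact test, adjusted p = 0.000177) and 2.22% against 1.33% for M1BP (1.67-fold, 0.0130). This background was matched on GC content but not on distance to a TSS. The pooled-list peaks it was drawn from had 27.0% of summits in promoters, against 54.5% of optimal peaks. Both elements lay mostly in promoter peaks, so these smaller differences cannot be told apart from the difference in promoter share. The same holds for the 7.24-fold and 10.9-fold differences, since a window 1000 bp from a promoter summit need not lie at a promoter. Promoters without an optimal peak were not compared as a group. Over the strongest 3915 peaks of each replicate the DRE share was 3.93% ± 0.390 at summits and 0.519% ± 0.0897 away from them (SD, n = 3). Both elements were features of promoter peaks: among the 1780 peaks over 500 bp from a TSS, 4 had a DRE against 9 distant windows, and 3 had an M1BP site against 4. GAGA factor repeats were at 6.56% of summits and 4.27% of distant points (exact test, adjusted p = 3.95e-05), but this call was lost without replicate 1 (adjusted p = 0.379) and without replicate 2 (0.105), with windows of 50 bp (0.337), among the peaks far from a TSS (0.451), among the 1957 peaks of highest signal (0.106) and among peaks supported by all 3 replicates (0.277). It held within 250 bp (17.4% against 9.09%, exact test, adjusted p = 3.23e-28), with the left window (1.95e-07), against GC-matched peaks (3.88e-08), with the window 2000 bp away (7.74e-10) and without replicate 3 (0.000864), and the GAGA share was higher at summits in 3 of 3 replicates. It was 7.92%, 6.90% and 4.96% in replicates 1, 2 and 3, against 4.24%, 4.29% and 4.06% in the distant windows. Without replicate 1 the GAGA share was 5.49% against 4.40%, and without replicate 2 it was 5.90% against 4.41%. These 2 sets held only 2296 and 2289 of the 3915 optimal peaks. Their lost calls therefore cannot be told apart from the use of fewer peaks. The CRE core TGACG (16.2% against 18.1%, exact test, adjusted p = 0.0925), the CAGCTG E-box (11.5% against 9.86%, 0.0814) and the Zelda motif (1.07% against 1.61%, 0.113) did not pass. TGACG passed, as lower at summits, against the window 2000 bp to the right (16.2% against 20%, exact test, adjusted p = 6.92e-05), against the window 1000 bp to the left (0.00633) and among peaks supported by all 3 replicates (0.0376). The CAGCTG E-box passed, as higher at summits, within 250 bp (exact test, adjusted p = 0.000366), against the left window (0.0147) and against GC-matched peaks (0.000676), and the Zelda motif passed, as lower at summits, within 50 bp (0.0216) and 250 bp (0.0181). Mean GC content was 39.3% at summits and 42.8% at the distant points, and against GC-matched pooled peaks TGACG stood at 16.2% and 15.7% (exact test, adjusted p = 0.733). The AP-1 site (1.81% against 2.09%), the CRE and C/EBP composite TGATGCAA (0.434% against 0.715%), the Xbp1 and CrebA site (0.460% against 0.613%), the CACGTG E-box (3.04% against 2.43%), the TATA box (1.79% against 1.23%), the initiator (19.1% against 18.0%) and both shuffled CRE controls (0.179% against 0.281% and 0.128% against 0.179%) did not pass.

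**Figure D3:**
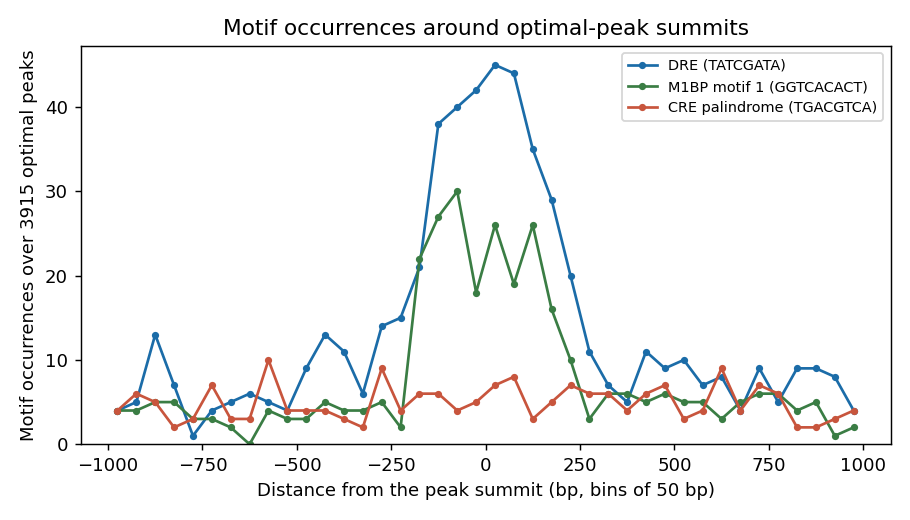
Occurrences of 3 motifs in bins of 50 bp at each distance (bp) from the summits of the 3915 optimal peaks. The DRE (blue) and the M1BP site (green) rise within 250 bp of the summit, and the CRE palindrome (red) stays at 10 or fewer per bin throughout.

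A search over all 8-mers put the DRE sequence TATCGATA first. Merged with their reverse complements, 531 8-mers were more frequent within 100 bp of the summit than at the point 1000 bp away and 638 were less frequent (exact McNemar test, adjusted p under 0.05). GC content differed between these windows (39.3% at summits, 42.8% at the distant points), and no GC-matched 8-mer search was run. How many of these 8-mers differ through base composition alone is therefore unknown. TAAAATAA (267 against 134 windows) was among the higher ones and GAGGAGGA (11 against 68) among the lower. The smallest p-values belonged to TATCGATA (152 against 21 windows), ATCGATAG (155 against 25), AGTGTGAC (113 against 14), GGTCACAC (126 against 20) and ATCGATAA (139 against 28). CACAGTGG (141 against 34), CACTGTGC (150 against 38), AACTATCG (89 against 11), GCTATCGA (90 against 12) and ACTATCGA (99 against 17) followed. The adjusted p of these 10 ran from 3.51e-21 to 4.86e-12. Among all palindromic 8-mers the CRE palindrome ranked 54 by the ratio of summit to distant windows, with 1 added to both counts, and its adjusted p was 0.610. The number of higher 8-mers fell to 255, 231 and 146 among peaks supported without replicates 1, 2 and 3, which left 2296, 2289 and 2503 peaks, and all 10 leading 8-mers stayed higher in each of these sets. Among the 1780 peaks over 500 bp from a TSS, 68 8-mers were higher, and 2 of the 10 leading ones, CACAGTGG (78 against 19) and CACTGTGC (83 against 19), were among them.

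Promoters of cytosolic ribosomal protein genes carried peaks far more often than other promoters. Of 13945 protein-coding genes, 2604 (18.7%) had an optimal peak within 500 bp of a TSS, and 72 of the 85 ribosomal protein genes did (84.7%, Wilson interval 75.6% to 90.8%), an odds ratio of 24.8 (95% interval 13.7 to 44.8, Fisher's exact test, two-sided, adjusted p = 1.85e-38 over 22 lists). In the 3915 strongest peaks of each replicate the number was 71.0 ± 1.0 (SD, n = 3). RpS27 (signal 1102, rank 61), RpL7 (980.7) and RpL14 (909.5) were the strongest. Among the 7925 genes with any pooled-list peak at a TSS, 72 of 81 ribosomal protein genes still carried an optimal peak, against 32.3% of the others (odds ratio 16.8, exact test, adjusted p = 1.48e-24).

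Genes of protein secretion and of the unfolded protein response, which acts when misfolded protein builds up in the endoplasmic reticulum, also passed. Of 38 secretory pathway genes 16 were bound (42.1%, odds ratio 3.18, exact test, adjusted p = 0.00801), TRAM (862.2), alphaCOP (709.5), the signal peptidase gene Spase22-23 (395.0) and Sec13 (379.9) among them. Of 12 unfolded protein response genes 7 were bound (58.3%, odds ratio 6.11, exact test, adjusted p = 0.0142), including Herp (359.8), the bZIP factor gene Xbp1 (359.3), the sensor kinase gene Ire1 (229.3) and the chaperone gene Calr (202.2). Both calls were lost among genes with a pooled-list peak (exact test, adjusted p = 0.280 and 0.265) among peaks supported by all 3 replicates (0.145 and 0.375) and among the 1957 peaks of highest signal (0.240 for both, with 7 of 38 and 3 of 12 bound). The secretory list was also lost without peaks that have a DRE or M1BP site (odds ratio 2.07, exact test, adjusted p = 0.174) and without replicate 2 (2.13, 0.290) or 3 (2.26, 0.151). The unfolded protein response list was lost without replicate 1 (odds ratio 3.89, exact test, adjusted p = 0.173), 2 (2.66, 0.476) or 3 (3.63, 0.151), and held without peaks that have a DRE or M1BP site (5.08, 0.0410). The sets without replicates 1, 2 and 3 held fewer peaks (2296, 2289 and 2503). In the 3915 strongest peaks of replicates 1, 2 and 3, 12, 14 and 16 secretory genes and 5, 7 and 7 unfolded protein response genes were bound. Chemoreceptor genes, taken as a silent control, had 0 of 119 promoters bound (upper Wilson limit 3.13%, exact test, adjusted p = 4.28e-10). Only 7 of them had a pooled-list peak, and within that background the list did not pass (exact test, adjusted p = 0.327). The chorion and accessory gland control had 0 of 19 (exact test, adjusted p = 0.111).

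Genes of the cAMP and CREB pathway had peaks at 8 of 23 promoters (34.8%, odds ratio 2.33, Fisher's exact test, adjusted p = 0.162), which did not pass. The bound members were the cAMP phosphodiesterase gene dnc (signal 667.9), the adenylyl cyclase genes Ac78C (570.4), Ac13E (318.8) and Ac76E (166.9), CrebB (399.4), the kinase genes Sik3 (306.8) and CaMKI (258.6), and Pka-C1, the catalytic subunit of protein kinase A (163.8). With promoters taken as 1000 bp around a TSS, 11 of 23 were bound and the list passed (exact test, adjusted p = 0.0249, against 0.0249 to 1 over the alternatives). Without replicate 1 or 2, which left 2296 and 2289 peaks, 4 of 23 were bound (17.4%). The odds ratios were 1.64 and 1.68 (exact test, adjusted p = 0.596 and 0.496). Without replicate 3 the number was 7 of 23 (odds ratio 3.18, exact test, adjusted p = 0.0758), among the 1957 peaks of highest signal it was 6 of 23 (3.25, 0.114), and among genes with a pooled-list peak the odds ratio was 1.17 (adjusted p = 1). The circadian clock list had 3 of 16 bound: the kinase genes sgg (806.7) and nmo (165.6) and the bZIP repressor gene vri (403.9). Of 19 bZIP factor genes 8 were bound (42.1%, exact test, adjusted p = 0.0680), led by Atf3 (1284.2) and REPTOR (862.0). The 8 include CrebB itself (399.4), whose promoter peaks replicate 3 did not support. The bZIP list was not tested with CrebB left out. The bZIP list passed among peaks supported by all 3 replicates, with 7 of 19 bound (exact test, adjusted p = 0.0101). It also passed without replicate 1, 2 or 3 (exact test, adjusted p = 0.0265, 0.0232 and 0.00740). It also passed with promoters of 1000 bp (exact test, adjusted p = 0.0397), among the 1957 peaks of highest signal (0.0111) and without peaks that have a DRE or M1BP site (0.0410). It did not pass with promoters of 250 bp (odds ratio 3.09, exact test, adjusted p = 0.0966) or among genes with a pooled-list peak (2.73, 8 of 14 bound, 0.303). With promoters of 500 bp the odds ratio of this list was 3.17.

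No other list passed. Gluconeogenesis and energy hormones had 7 of 16 genes bound (Thor, InR, PCB and bmm strongest, exact test, adjusted p = 0.0680), but 2 of 16 without replicate 1 or 2 and 3 of 16 without replicate 3. The share of other genes bound was 11.4%, 11.1% and 12.1% without replicates 1, 2 and 3. The activity-regulated genes had 3 of 8 bound (puc, kay and Hr38, exact test, adjusted p = 0.297), heat shock proteins 6 of 19 (Hsp83 and Hsp27, 0.294), the vacuolar ATPase 10 of 33 (Vha55 and Vha100-2, 0.249) and translation initiation factors 13 of 44 (eIF6 and eIF4EHP, 0.193). Mitochondrial ribosomal proteins had 18 of 73 (mRpS23 and mRpS10, 0.332), oxidative phosphorylation 17 of 87 (ND-ASHI and ND-MWFE, 0.955), the proteasome 7 of 48 (Rpn3 and Rpt5, 0.796) and the cell cycle list 7 of 34 (Dp and dup, 0.955). Lists of tissue and stage genes stood close to or below the 18.7% of all genes, or above it without passing: embryonic patterning 3 of 35 (hb, hry and Dfd, 0.297), neuronal differentiation 3 of 19 (elav and pros, 1), muscle 3 of 17 (sls and Mef2, 1), germline 3 of 14 (orb and exu, 0.95), and fat body, gut and hemocyte 5 of 15 (Hnf4 and cad, 0.297).

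**Figure D4:**
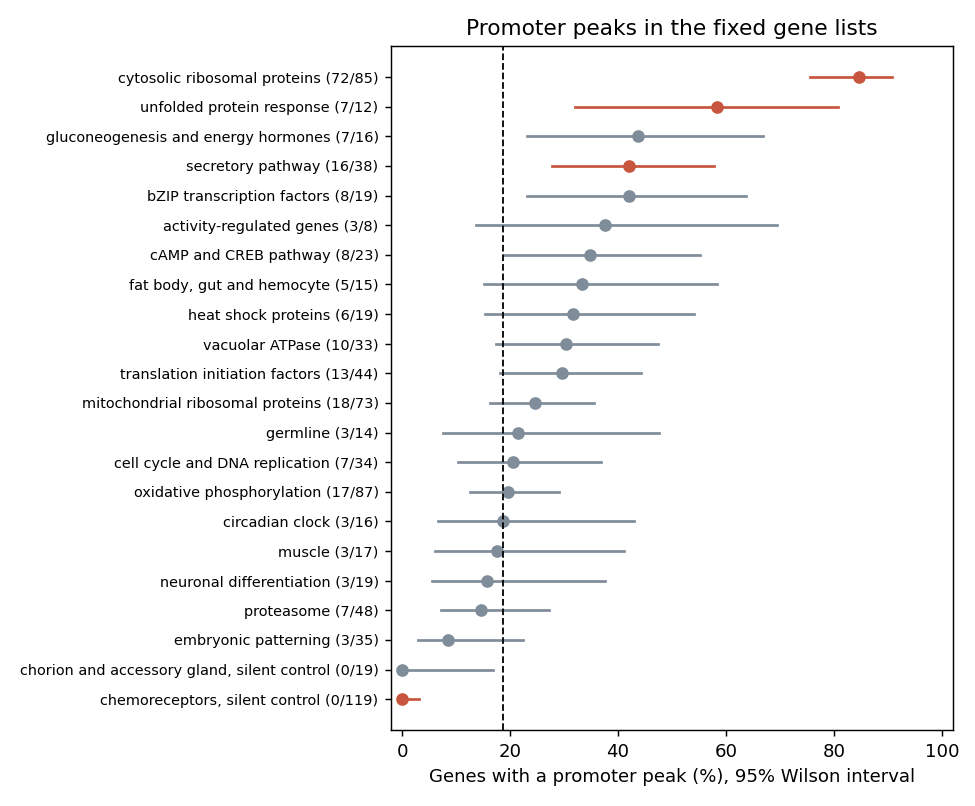
Share of genes (%) with an optimal peak within 500 bp of a TSS in each of the 22 lists, with 95% Wilson intervals and counts of bound and all members, and lists with an adjusted p under 0.05 in red. The dashed line is the share over all protein-coding genes (18.7%), and the cytosolic ribosomal proteins stand at 84.7%.

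Chromosome X held 610 optimal peaks, 25.9 per Mb, and chromosome arms 2L, 2R, 3L and 3R held 28.9 to 32.4 per Mb. The X to autosome ratio was 0.859 (exact 95% binomial interval 0.786 to 0.936). In the pooled list X also held fewer peaks than 2L, an arm of the same length (4655 against 5619, both 23.5 Mb). A lower number on X was thus not particular to the optimal peaks. Per protein-coding gene the ratio for optimal peaks was 0.986 (0.902 to 1.07). Among peaks supported by all 3 replicates it was 0.934 (0.827 to 1.05), so both of these intervals held 1. The fourth chromosome had 16 peaks, 11.9 per Mb.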

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

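The windows 2000 bp to the right, the peaks without a DRE or M1BP site and the cAMP list without CrebB were chosen after seeing the data; the other alternatives were planned. Samples could not be paired between groups, because there was 1 group. The motif tests against distant windows were paired by peak. Summit and distant shares were not tested as pairs over the replicates. Of 72 alternatives to the results of the design, 56 left the result in place, 15 moved it and 1 reversed it. The promoter share stayed 27.5 to 43.1 percentage points above its background under every alternative run. For single motifs 123 of 154 alternatives left direction and call in place, for single lists 153 of 199, and for the replicates that support a named peak 163 of 175.

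Supported peaks numbered 1104 with the first 1957 ranks of each replicate and 3052 with the first 7830, which follows from fewer or more ranks being read. The median pairwise IDR count was 2536 at an IDR of 0.01, a stricter threshold by construction. Correlation was 0.655 as Pearson's r of log2 signal, and 0.499 to 0.686 without 1 replicate; the cause was not tested. The X to autosome ratio was 0.986 per gene and 0.890 to 0.948 without 1 replicate; the cause was not tested. The difference in CRE share was -0.0255 points with the window 2000 bp away; the cause was not tested. Higher 8-mers numbered 154 within 50 bp, 68 over 500 bp from a TSS, 180 among the 1957 peaks of highest signal, 153 among peaks supported by all 3 replicates and 146 to 255 without 1 replicate; the cause was not tested. With genes that have a pooled-list peak as background, 1 list passed, cytosolic ribosomal proteins, out of fewer genes tested.

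These differences reversed, in percentage points, and for none of them was the cause tested. AP-1 turned to 0.0766 within 50 bp, 0.485 within 250 bp and 0.0255 at 2000 bp, and lay between -0.481 and 0.0799 without 1 replicate. The Xbp1 and CrebA site turned to 0.102 with the left window. Against GC-matched peaks TGACG turned to 0.536, the Xbp1 and CrebA site to 0.153, Zelda to 0.230, the TATA box to -0.281 and the shuffled CTGATCAG to 0.0255. Over 500 bp from a TSS the DRE turned to -0.281, M1BP to -0.0562, the CAGCTG E-box to -1.74 and the shuffled GATCGATC to 0.0562. The initiator turned to -0.204 among the 1957 peaks of highest signal and lay between -0.131 and 1.08 without 1 replicate, and CTGATCAG between -0.0874 and 0.0400.

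The germline list turned to -1.61 at 250 bp, -0.0774 at 1000 bp, -5.59 with the pooled-peak background, -2.68 among the 1957 peaks of highest signal, -2.53 among supported peaks and -2.20 without DRE or M1BP peaks. With the pooled-peak background the clock list turned to -11.4, mitochondrial ribosomal proteins to -3.86, oxidative phosphorylation to -4.07 and the cell cycle list to -7.89. Among the 1957 peaks of highest signal oxidative phosphorylation turned to -4.10, the vacuolar ATPase to -0.735 and the fat body list to -3.16. Among supported peaks oxidative phosphorylation turned to -5.10 and the cell cycle list to -0.845. Without DRE or M1BP peaks initiation factors turned to -0.572 and muscle to 1.17. Without 1 replicate the germline list lay between -4.99 and 2.88, oxidative phosphorylation between -5.26 and -3.38, mitochondrial ribosomal proteins between -0.453 and 5.71, the cell cycle list between -2.33 and 2.59 and muscle between -5.53 and 5.53. Without CrebB the cAMP list had 7 of 22 genes bound (Fisher's exact test, unadjusted p = 0.164). The read depth is unknown, so what depth limits could not be given.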

Other observations

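The tests of input DNA, of broadly expressed groups, of an extra copy and of gene length, and the peaks and gene classes named in the last paragraph, were chosen only after the results were seen. The 250 bp window was planned, but the limit of 1.5 on its ratio was set after its value was known, in place of an earlier 3. The check of the GC-matched background on the DRE was added after its values were seen. No biological explanation named by the design was tested, since it has 1 group.

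The CRE palindrome was not detectably more frequent at CrebB summits. Summits lying up to 250 bp from the bound site stay open: the ratio was 1.31 (51 against 39 windows, 95% interval 0.845 to 2.04, exact McNemar test, adjusted p = 0.369), which holds both no enrichment and a modest one. Base composition stays open too: against GC-matched peaks the odds ratio was 1.096 (23 against 21 peaks, 0.605 to 1.98, Fisher's exact test, p = 0.880), under the 3 set in advance, but this background of other pooled-list peaks also took the DRE from 7.24-fold to 1.75-fold, so it could hide an enrichment. Input DNA, as the description label has it, cannot be told apart from ChIP here: 50.04% of optimal peaks recurred in all 3 replicates, and input of open chromatin could recur as well. Peaks were called against 1 control alignment, and 7200, 6416 and 6274 peaks of replicates 1, 2 and 3 had a q-value under 0.01. No reads were examined, so how the control differs from these libraries is unknown.

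Ribosomal protein promoters carried peaks far more often than others. A peak at every broadly expressed group is argued against by the proteasome (odds ratio 0.743) and oxidative phosphorylation (1.06) lists, whose higher upper limit was 1.80. Translation initiation factors (1.83, 0.957 to 3.50) and the vacuolar ATPase (1.90, 0.902 to 3.99) had wider intervals and did not pass. The interval of the ribosomal protein list, 13.7 to 44.8, lay above all of these. Expression was not measured, so a smaller excess at broadly expressed groups stays open. The lists were not matched on level of expression, so they do not test whether peaks follow that level. DRE or M1BP sites may contribute: 27 of 75 ribosomal protein promoter peaks had one (36.0%), against 199 of 2060 others (9.66%), an odds ratio of 5.26 (3.21 to 8.62, Fisher's exact test, p = 1.97e-09). Exact sites within 100 bp of the summit do not account for all of it. Without peaks that have such a site 48 of 85 ribosomal protein genes stayed bound (odds ratio 6.69, Fisher's exact test, adjusted p = 1.04e-15, against 1.4e-46 to 1.04e-15 over the alternatives). Sites further out or with a mismatch were not counted. Over all optimal peaks, DRE windows rose from 152 to 285 and M1BP windows from 87 to 188 when 250 bp were searched. What these elements leave unexplained therefore stays open.

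CrebB carried 7 optimal peaks. Gene length is argued against: 2 of 668 genes of similar length (0.299%) had as many. This count takes all optimal peaks, while all 3 replicates supported only 2 of the 7. It includes a peak with its summit 169 bp upstream of the gene. Genes were matched on length but not on their number of TSSs. An extra copy of the locus on the transgene cannot be told apart from binding, because the insert's length is not given in the sources used here. The denser 10000 bp beside the gene held 6 pooled-list peaks and the other side 5, and 11.9% and 18.0% of windows beside genes were as dense.

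Peaks far from a TSS included the strongest of the optimal list. Rank 1 (2L, 6612370 to 6612919, signal 3466), rank 2 (2962) and rank 8 (2183) all lay in introns. The TSS nearest to rank 1 was of CG11050. Rank 2 lay 1408 bp upstream of its nearest TSS, of cbt, and rank 8 lay 965 bp upstream of its nearest TSS, of Lk6. Among other gene classes, 16 of 290 tRNA genes (5.52%), 21 of 269 snoRNA genes (7.81%) and 36 of 5809 transposable elements (0.620%) had an optimal peak within 500 bp of their start. The ncRNA genes stood at 194 of 3261 (5.95%). No share at random positions was computed for these classes, so none of them can be called high or low.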
